A study of Mus musculus with 7 samples.

How the data were processed

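The series holds 7 mouse samples, of which 3 are single-cell RNA libraries with files and 4 are Ascl1 ChIP-seq samples with none, so the latter were left out. The deposited matrices hold the count of unique molecules (UMIs) per gene and cell, without normalisation, and the deposited barcode and gene lists hold no measurement (other). Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger, version 3.0.2 for the early libraries, and Seurat is named for the sorted library without a stated role or version. The sorted ANTSi library came from 4 mice (8 eyes) after papain digestion and a GFP sort, with 44000 cells captured for a target of 4000. How many animals the early libraries hold is not stated. Gene positions are from the RefSeq annotation of GRCm38.p6.

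Depth per library was 9558749 UMIs for sorted ANTSi, 22405666 for early ANTSi and 3130938 for early ANT. Cells with fewer than 200 genes or more than 20% mitochondrial counts were removed, 110 of sorted ANTSi for mitochondrial counts alone. In early ANT, 356 cells fell under the gene minimum. Scrublet, run per library through scanpy, called 35 of 2542 sorted cells doublets (1.38%), 3 of 3838 early ANTSi cells and 0 of 3536 early ANT cells. With so few calls it in effect removed no doublets from the early libraries, so mixed droplets stay in them. Kept cells had median counts of 3624, 5323 and 825.

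Analyses ran in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, statsmodels 0.14.6 and matplotlib 3.10.9. For clustering only, early ANTSi cells were thinned binomially so that the median equalled that of early ANT, and both early libraries were clustered together. The sorted library was clustered alone. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen without the gene lists, and 30 principal components, 15 neighbours and Leiden resolution 1 were used, with seed 1.

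Clusters were named from 21 marker lists, with leading genes ranked by fold (pseudocount 20 CPM) among genes expressed in at least 10% of cells. A first step named rod-like, cone-like and microglia or macrophage-like clusters, with at least 5 class markers among the 10 leading genes against all other cells. The rest were compared with the mean of those classes. Among classes with at least 3 markers at least 2-fold above that mean, the one with most markers among the 10 leading genes was taken. Ties went to the class with more markers past 2-fold. Clusters with Müller glia markers but led by Neurog2 or Ascl1 were kept apart. Neuron-like cells of the sorted library are the bipolar-like and immature neuron-like clusters. Sex was read from Xist and 4 Y-linked genes, and a cell with counts of only 1 kind was assigned. In early ANTSi, 63 cells had both kinds and 590 had neither.

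Counts of all kept cells of a class were summed without thinning and scaled to an equal sum for each class and library (CPM). With 1 library per group, no test, p-value or number of changed genes was computed. Ratios have exact 95% Poisson intervals and shares have exact Clopper-Pearson intervals, all for counting error only. A gene with 0 counts was set at a floor of 3 counts for its class sum, and a fold against it is written as at least that fold, though the 95% lower limit of the ratio can lie under it. For each of 18 gene lists, members with at least 10 CPM in 1 group gave a median log2 ratio where at least 3 were measured. Its percentile came from 10000 random lists of the same size, matched in 20 bins of expression, and lists outside the central 95% are called outside the random range. Genes of a list are not independent replicates. Classes with at least 50 cells in each early library were compared, and microglia or macrophage-like cells, the class that the labels name, were compared with 40 cells in early ANT.

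Named genes are Ascl1, Stat3, Socs3 and Id1, up to 4 members per list (the 2 highest and 2 lowest ratios), and the 10 highest and 10 lowest other genes with at least 50 CPM in 1 group, at least 100 counts and an interval beyond 1.5-fold. Not every gene so chosen is printed. Hes5 and Rho levels beside other classes, Neurog2 and Otx2 over whole libraries and the lead genes of clusters were named after their values were seen. Filters, marker lists, gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The naming steps for clusters, which went through several versions, the separation of Neurog2-led cells and the split by sex were chosen after seeing the data.

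The other settings fixed beforehand were Leiden resolutions of 0.5 and 2, doublets kept, at least 500 genes, each early library clustered alone, gene lists kept in the clustering, scaling by the median of ratios, cells thinned to 400 UMIs, the mean over cells, totals without rod, cone, mitochondrial and ribosomal genes, and members with at least 50 CPM. Settings added after seeing the data were Neurog2-led cells counted as Müller glia-like, clusters weighted alike, at least 5 expected counts, female or male cells alone, early ANTSi cells thinned to the depth of the early ANT cell of like rank before clustering, both libraries clustered together without thinning, and leaving out the cell cycle cluster or the cell with most MHC class II counts.

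The pipeline was tested on simulated data. Apart from planted shifts, counts held only counting error around a mean profile, or a mean profile per class for simulated cells. Differences between animals, between libraries and among cells of a class were left out. The values below thus check the calculation, not how far real libraries vary. Intervals covered the true ratio for 95.8% of genes at the size of whole early libraries and 98.2% at that of a small class. Lists with a planted shift fell at percentiles 0 and 0.12, and 0 of 15 and 0 of 16 other lists fell outside the random range. A planted 4-fold increase in a small class was detected for 95.2% of genes and a decrease to 0.25-fold for 65.9%, but a 2-fold increase for 45.5% and a decrease to 0.5-fold for 34.7%. At the depth of early ANT, planted shares of 11.1% bipolar-like and 17.8% Neurog2-led cells were found as 10.4% and 17.5%, with 91.6% and 82.7% of the planted cells in their own class, while rods planted at 0.537% were not found.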

Results

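The files used were 3 droplet libraries of single mouse retinal cells (10x Genomics), 1 library per group, so no value has a replicate error. In the study's scheme, ANT stands for Ascl1 (a proneural transcription factor) expressed in Müller glia, NMDA (which damages neurons) and TSA (a histone deacetylase inhibitor), and ANTSi adds an inhibitor of the STAT pathway. Early ANT and early ANTSi were libraries from an early time that the labels do not state, and their labels name retinal microglia. Sorted ANTSi came from GFP-positive cells of 4 adult mice (8 eyes), pooled and sorted. The 4 ChIP-seq samples had no files to analyse. The sorted ANTSi file held 2652 cells with 9558749 unique molecules (UMIs) and a median of 3560.5 per cell. The early ANTSi file held 3952 cells with 22405666 UMIs and a median of 5258.5, against 3907 cells, 3130938 UMIs and a median of 779 in early ANT. After filtering, 2507 sorted ANTSi, 3835 early ANTSi and 3536 early ANT cells remained, and the early ANTSi median was 6.45 times that of early ANT. Intervals are 95% and cover counting error only, so they leave out differences between animals and between preparations.

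The comparison of early ANTSi with early ANT addresses whether the STAT inhibitor goes with another mix of cells and other gene levels. Despite the labels, most cells of both libraries carried Müller glia markers: 65.4% in early ANTSi (63.9 to 66.9%, exact Clopper-Pearson; 2509 cells) and 83.8% in early ANT (82.6 to 85.0%; 2964 cells). Bipolar-like cells, in a cluster led by Neurod4, Igfbpl1, Isl1 and Otx2, were 10.4% in early ANTSi (9.41 to 11.4%; 397 cells) and 3.17% in early ANT (2.62 to 3.8%; 112 cells), a ratio of 3.27. Over whole libraries, however, most bipolar markers were lower in early ANTSi, among them Grm6, Pcp2 and Trpm1, while Otx2 and Isl1 were higher. A glia-like cluster led by Sct, Neurog2 and Ascl1, kept apart here as Neurog2-led, was 19.1% in early ANTSi (17.9 to 20.4%; 734 cells) and 6.84% in early ANT (6.03 to 7.73%; 242 cells), a ratio of 2.80. Microglia or macrophage-like cells (C1qa, Ctss, Hexb) were 4.25% (3.63 to 4.94%; 163 cells) and 1.13% (0.809 to 1.54%; 40 cells). Rod-like cells were 0.365% in early ANTSi (14 cells) and 4.16% in early ANT (147 cells), and cone-like cells were 0.469% and 0.877%. Rods are the most abundant cells of the retina, so these shares describe the cells captured and not the makeup of the retina. Whether cells were selected alike in both libraries was not tested.

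The early ANTSi library held cells of both sexes, and early ANT held no Y-linked RNA. Early ANT had 0 counts of 4 Y-linked genes in 3536 cells and 4368 counts of Xist, the RNA expressed from the inactive X chromosome of females. Early ANTSi had 1106 Y-linked and 30489 Xist counts, with Y-linked RNA alone in 570 cells and Xist alone in 2612 cells. Within early ANTSi, bipolar-like and Neurog2-led cells together were 10.9% of male cells (8.44 to 13.7%; 62 cells) and 38.0% of female cells (36.2 to 39.9%; 993 cells). In early ANT they were 10.0%. Müller glia-like cells were 86.7% of male cells (83.6 to 89.3%) and 57.0% of female cells (55.0 to 58.9%). With male cells alone set against early ANT, the difference in Müller glia-like share was 2.84 points in place of -18.4, and that in bipolar-like share was -0.18 points in place of 7.18. The split of bipolar-like from Neurog2-led cells was also unstable: with doublets kept, the Neurog2-led cluster was not found, and the bipolar-like difference was 14.9 points. That setting returned only 3 cells to early ANTSi and 0 to early ANT, so the split changed with almost the same cells.

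**Figure D1:**
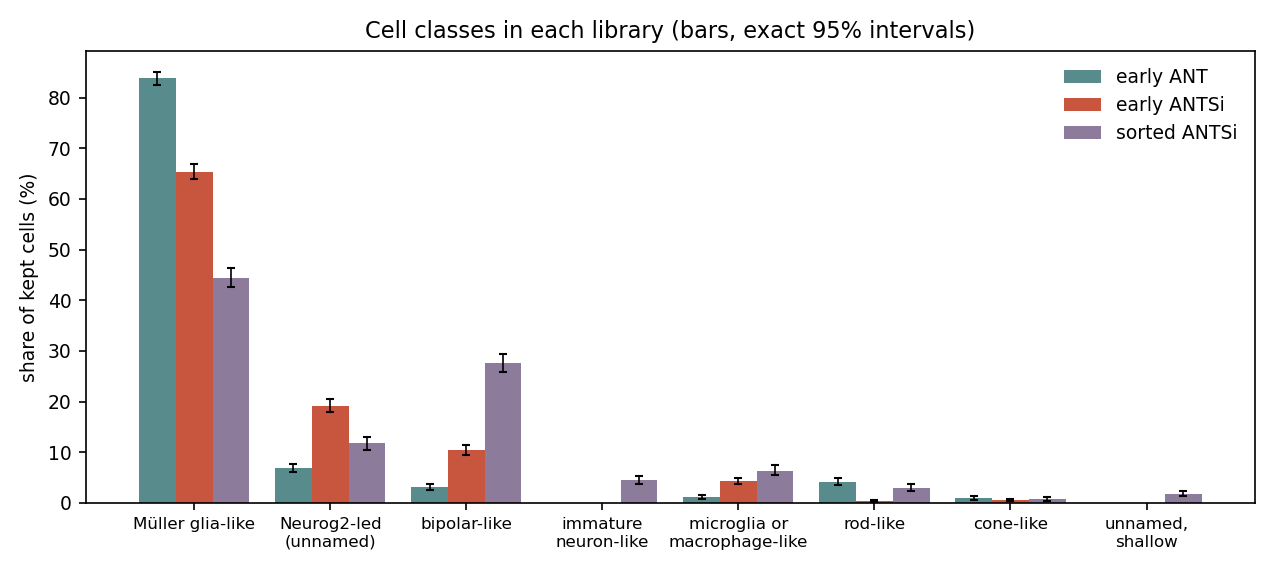
Share of kept cells in percent (vertical axis) for each cell class (horizontal axis) in early ANT, early ANTSi and sorted ANTSi, 1 library each, with bars as shares and whiskers as exact 95% intervals. Müller glia-like cells were 83.8% of early ANT, 65.4% of early ANTSi and 44.5% of sorted ANTSi.

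**Figure D2:**
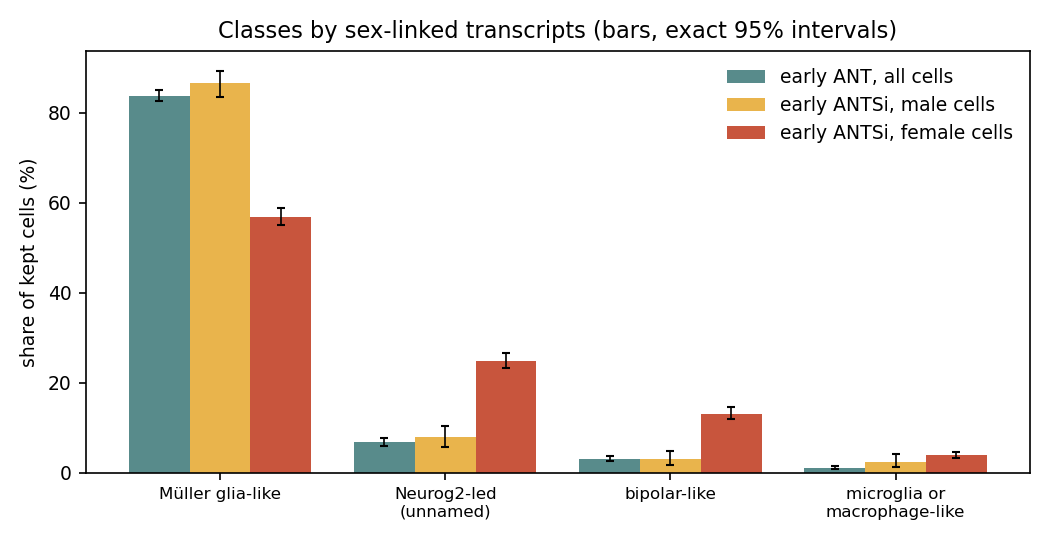
Share of cells in percent (vertical axis) for 4 cell classes (horizontal axis) in early ANT and in the male and female cells of early ANTSi, with bars as shares and whiskers as exact 95% intervals. Neurog2-led cells were 6.84% of early ANT, 7.89% of male cells and 24.8% of female cells of early ANTSi.

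In Müller glia-like cells, all measured Id and MHC class I genes, 9 of 12 Notch targets and glial regulators and 12 of 18 immediate early and heat shock genes were lower in early ANTSi than in early ANT, and all measured cell cycle genes and 7 of 12 gliosis genes were higher. Id1 and Id3, inhibitors of bHLH transcription factors, stood at 2716 and 3169 CPM (counts scaled to an equal sum for each class and library) in early ANTSi against 4661 and 6358 in early ANT, 1.72-fold lower (1.68 to 1.75) and 2.01-fold lower (1.97 to 2.04). The MHC class I gene H2-D1 was 336 against 963 CPM, 2.87-fold lower (2.73 to 3.01). The Notch target Hes5 was 632 against 1749 CPM, 2.77-fold lower (2.67 to 2.87). The intermediate filament gene Gfap was 1124 against 398 CPM, 2.83-fold higher (2.65 to 3.01), and the proneural gene Neurog2 was 37.7 against 12.1 CPM, 3.11-fold higher (2.16 to 4.62). Over whole libraries Neurog2 was 106 against 21.1 CPM, so RNA of Neurog2-led cells in these droplets is not excluded as its source.

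Of the 4 genes fixed for every class, Socs3, a feedback inhibitor of STAT signalling, was 1585 CPM in early ANTSi and 1234 in early ANT, 1.28-fold higher (1.24 to 1.33). Stat3 was 123 against 153 CPM, 1.24-fold lower (1.11 to 1.38). Ascl1 was 89.0 against 113 CPM, 1.26-fold lower (1.11 to 1.44), but its log2 ratio was 0.19 when the Neurog2-led cells were counted as Müller glia-like. On the mm10 assembly, Ascl1 (ENSMUSG00000020052) lies on chromosome 10 from 87490819 to 87493660 and Stat3 (ENSMUSG00000004040) on chromosome 11 from 100886806 to 100939594. Socs3 (ENSMUSG00000053113) lies on chromosome 11 from 117966079 to 117970336 and Id1 (ENSMUSG00000042745) on chromosome 2 from 152736251 to 152737410. Neurog2 (ENSMUSG00000027967) lies on chromosome 3 from 127632733 to 127635636 and Hes5 (ENSMUSG00000048001) on chromosome 4 from 154960626 to 154962372.

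By list, all 4 Id genes were lower in the Müller glia-like cells of early ANTSi, with a median log2 ratio of -0.89, at percentile 0.01 of 10000 random lists of like expression. All 10 measured MHC class I genes were lower (median -0.93, percentile 0), among them H2-Q7 (3.02-fold lower, 2.47 to 3.68) and the immunoproteasome gene Psmb8 (1.49-fold lower, 1.36 to 1.64). Of 12 Notch targets and glial regulators, 9 were lower (median -0.50, percentile 0), with Heyl 2.36-fold lower (1.93 to 2.87) and Notch2 1.27-fold higher (1.06 to 1.52). Of 18 immediate early and heat shock genes, 12 were lower (median -0.38, percentile 0.02; -0.60 to 0.0048 over resampled genes), with Nr4a1 2.08-fold lower (1.96 to 2.21) and Klf2 4.51-fold higher (2.70 to 8.14). Of 12 gliosis genes, 7 were higher (median 0.25, percentile 98.3), with S100a6 2.56-fold higher (2.43 to 2.69) and Lcn2 2.97-fold lower (2.65 to 3.32). The gliosis median stayed outside the random range in only 10 of 15 alternatives, with 0.046 the lowest.

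All 13 measured S phase genes (median 0.85, percentile 100) and all 12 measured G2 and M phase genes (median 2.97, percentile 100) were higher in Müller glia-like cells of early ANTSi. Cenpf, a kinetochore gene, was 12.6-fold higher (7.15 to 24.4), Ube2c 16.3-fold higher (6.93 to 50.4), and the ribonucleotide reductase gene Rrm2, with 0 counts in early ANT, at least 8.67-fold higher against a floor of 3 counts over the class (95% lower limit of the ratio 6.96). A cluster with Cenpf, Cks2 and Cdc20 among its leading genes, after S100a10, Vim, Gal and Lgals1, held 144 Müller glia-like cells of early ANTSi and 19 of early ANT. Without it, too few G2 and M phase genes were measured for a median and the S phase median was 0.11 (percentile 96.4). With each cluster weighted alike in both libraries, the G2 and M phase median was -0.59.

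The other lists lay within the range of random lists in Müller glia-like cells. JAK-STAT targets and feedback genes had a median of -0.17 (percentile 17.9; 7 of 15 higher), with Socs1 2.07-fold lower (1.73 to 2.46). Interferon-stimulated genes had a median of -0.12 (percentile 20.6; 8 of 18 higher), with Stat1 2.43-fold lower (2.17 to 2.72) and Bst2 1.39-fold higher (1.28 to 1.51). This last median was 0.36 with clusters weighted alike, 0.55 with each library clustered alone, 0.48 with female cells of early ANTSi alone and -2.54 with male cells alone. Medians were 0.04 for neurogenic Ascl1 targets (percentile 76.2), 0.23 for inflammatory cytokines (93.2), -0.21 for homeostatic microglial genes (20.0), 0.01 for disease-associated microglial genes (44) and -0.34 for cholesterol synthesis (7.85). They were 0.06 for glycolysis and hypoxia (66.8), 0.06 for the unfolded protein response (75.1) and 0.05 for lysosome and phagocytosis (78.1). Of the MHC class II genes only H2-Ab1 was measured, at 22.4 CPM in early ANTSi and 23.5 in early ANT.

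**Figure D3:**
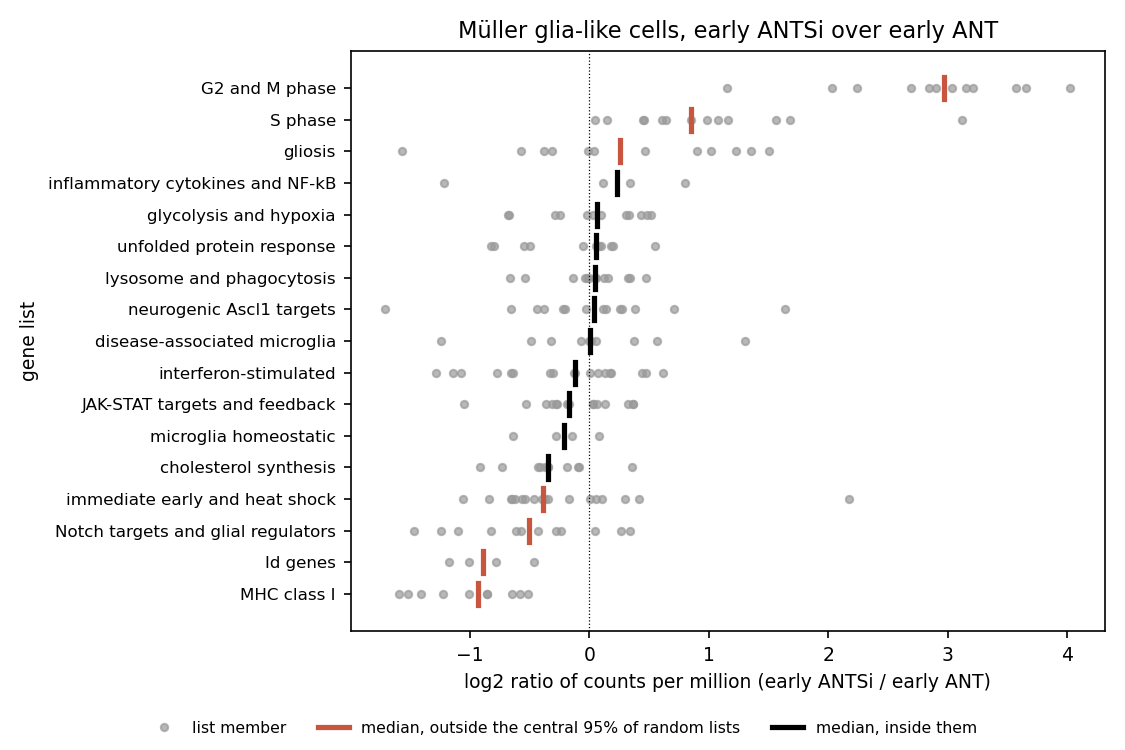
Log2 ratio of CPM, early ANTSi over early ANT, in Müller glia-like cells (horizontal axis) for each gene list (vertical axis), with points for list members and bars for medians, 1 library per group. Medians outside the central 95% of random lists are coloured, from -0.93 for MHC class I to 2.97 for G2 and M phase.

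Outside the lists, Lgals1, which encodes galectin-1, had the highest ratio of the genes that met the rule in Müller glia-like cells, 5.93-fold higher in early ANTSi (5.41 to 6.52). Cks2, a regulator of cyclin-dependent kinases, followed at 5.08-fold (3.55 to 7.52), but its log2 ratio was -0.62 with clusters weighted alike. Scx, Selenoh, A2m, S100a10, S100a11, the neuropeptide gene Gal, Uchl1 and Sarnp were 2.41-fold to 3.08-fold higher, with Gal at 7058 against 2879 CPM. Zbtb8b was 34.3-fold lower (26.8 to 44.3). Clstn1, the immediate early gene Arc, Sertad2, the interferon-induced GTPase genes Gbp2b and Irgm1, Cnnm3 and Zfp746 were 2.93-fold to 3.59-fold lower. AY036118 was 12.8-fold lower here, 10.9-fold in Neurog2-led and 8.48-fold in bipolar-like cells, and Lars2 was 3.57-fold and 3.35-fold lower in the first 2, so a difference in RNA or preparation between the libraries is not excluded for them. The clusters that filled the class differed: a cluster led by Rlbp1 and Hes5 held 1080 of its cells in early ANT and 340 in early ANTSi, and a cluster led by Clu and Dio2 held 391 and 702. An Ifit3-led cluster, with Irgm1 and Gbp2b among its leading genes, held 427 in early ANT and 197 in early ANTSi, so its unequal share enters the folds of these 2 genes. RNA of rods was also unequal in this class, with Rho at 52.9 CPM in early ANTSi and 130 in early ANT.

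In Neurog2-led cells, Neurog2 was 323 CPM in early ANTSi and 117 in early ANT, 2.77-fold higher (1.87 to 4.30), and Ascl1 was 446 against 667 CPM, 1.49-fold lower (1.25 to 1.77). With only cells of at least 500 genes, the Ascl1 log2 ratio was 0.16. All 4 Id genes were lower (median -0.75, percentile 0.10), with Id1 at 2388 against 3893 CPM, and 13 of 18 immediate early and heat shock genes were lower (median -0.43, percentile 0.03). With male cells of early ANTSi alone, the Id median was -0.33 and that of immediate early and heat shock genes 0.039. Interferon-stimulated genes were higher in 12 of 18 (median 0.59, percentile 100), with Isg15, a ubiquitin-like modifier, 4.20-fold higher (2.27 to 8.79) and Ifit3 3.06-fold higher (1.85 to 5.49). This median was -1.86 with male cells of early ANTSi alone and -0.43 with the gene lists kept in the clustering. Gliosis genes had a median of 0.49 (percentile 97.6), with Gfap 3.30-fold higher (2.68 to 4.12), but -0.064 with cells thinned to equal depth, and stayed outside the random range in only 2 of 10 alternatives. Hes1, a Notch target, was 4.20-fold lower (2.93 to 5.88) in a list with a median of -0.35 (percentile 2.87). Socs3 was 1010 against 835 CPM and Stat3 125 against 172. A2m had 918 counts against 1, a ratio of 41.5 (7.43 to 1641), and Sct, Gal and Tmsb4x were 2.17-fold, 2.07-fold and 1.66-fold higher. JAK-STAT genes (median -0.18, percentile 25.4), MHC class I genes (-0.04, 56.9) and neurogenic Ascl1 targets (-0.20, 13.2) lay within the range of random lists. Outside it lay JAK-STAT genes with male cells alone (0.53, percentile 99.3) and MHC class I genes with at least 500 genes per cell (-0.63, percentile 0.355). Neurogenic Ascl1 targets lay outside it in 1 of 10 alternatives. Of 8 MHC class I genes, 5 were lower and 3 higher. H2-D1 was 188 against 620 CPM, 3.29-fold lower (2.72 to 3.96), H2-K1 1.54-fold lower (1.20 to 1.95) and Psmb8 2.84-fold higher (1.20 to 8.81).

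In bipolar-like cells of early ANTSi, Sncb, which encodes beta-synuclein, was 9.97-fold lower than in early ANT (6.78 to 14.5), Pcp4 4.81-fold lower (3.96 to 5.81; 299 against 1441 CPM) and the synaptic complexin gene Cplx3 3.77-fold lower (3.11 to 4.55). Sct was 4.79-fold higher (2.84 to 8.77), Mybl1 3.52-fold higher (1.85 to 7.74) and Neurog2 3.01-fold higher (1.16 to 11.1). The class was a single cluster with 6 bipolar and 5 immature neuron markers past the 2-fold bound. Whether it held another mix of cells in each library was not tested, so these folds may not be changes within like cells. Hes5 was 12.1-fold lower (7.09 to 20.3; 46 against 24 counts), but at 260 CPM in early ANT it stood near the 186 CPM of microglia-like cells there, so RNA of glia in the droplets is not excluded as its source. Of 18 neurogenic Ascl1 targets, 13 were higher (median 0.27, percentile 97.8), and of 13 interferon-stimulated genes, 8 were higher (median 0.28, percentile 99.2). These stayed outside the random range in only 5 and 6 of 12 alternatives, and both directions turned elsewhere, with -0.29 for the neurogenic list and -0.075 for the interferon list when each library was clustered alone. Homeostatic microglial genes had a median of -0.73, which was high among random lists (percentile 97.6), since the median of those lists was -1.37. With cells thinned to equal depth, the homeostatic median was 0.80. Id1 was 1157 against 802 CPM, 1.44-fold higher (1.15 to 1.84), and Socs3 224 against 108 CPM, 2.07-fold higher (1.12 to 4.35). Both turned when each library was clustered alone, with log2 ratios of -0.64 and -0.65. Of 4 Id genes, however, 3 were lower, but only Id3 beyond counting error, at 373 against 932 CPM, a ratio of 0.401 (0.321 to 0.507). Id2 had a ratio of 0.988 (0.411 to 3.10) and Id4 of 0.258 (0.0753 to 1.37). Id3 stood higher in Müller glia-like cells of both libraries, so RNA of glia in the droplets is not excluded as its source. The Id median was -0.67 (percentile 5), within the range of random lists. It stayed negative in 10 of 10 alternatives and lay outside the random range in 4 of them. Of 8 MHC class I genes, 5 were lower and 3 higher (median -0.46, percentile 29.1), with H2-D1 at 125 against 336 CPM, 2.68-fold lower (1.79 to 3.90). The class rested on 92322 UMIs in early ANT, where a gene with 0 counts was set at 32.5 CPM. A gene with 1 count there stood at 10.8 CPM and so passed the bound of 10 CPM. Members of lists could thus enter through 1 count in early ANT, so numbers of lower genes lean upward.

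In microglia or macrophage-like cells, 19 of 23 interferon-stimulated genes were lower in early ANTSi (median -0.97, percentile 0.03) and 9 of 10 MHC class I genes were lower (median -0.76, percentile 0.28), with H2-K1 at 783 against 2377 CPM, 3.04-fold lower (2.44 to 3.75). The MHC class II median was -4.02 (percentile 0). These medians leaned on 1 cell of early ANT, which held 113 of the 165 MHC class II counts of its 40 cells. Without it they were -0.38 (percentile 23.3), -0.49 (3.62) and -3.47 (0). The MHC class II median still cannot be read as a level of the class, since another cell held 27 of those counts, only 19 of the 40 cells had any, and 2 of 6 members were higher (-5.96 to 0.74 over resampled genes). Lyz2, which encodes lysozyme, was 2.22-fold lower (1.55 to 3.10), the immunoproteasome gene Psmb10 3.17-fold lower (1.74 to 5.40), Spp1 1.76-fold higher (1.20 to 2.68) and the NF-kB inhibitor gene Nfkbia 1.86-fold higher (1.27 to 2.84). The cell with 113 MHC class II counts also held 12 of the 39 Lyz2 counts of early ANT, and had 0 counts of the microglial genes Hexb and P2ry12. Of 43 gene ratios computed without that cell, 41 stayed the same, 2 moved and 0 reversed. The values of the folds above without that cell are not given here, so their size without it stays open. Lysosomal genes had a median of -0.36 (percentile 2.05), which lay within the random range without that cell (percentile 3.15). G2 and M phase genes had a median of 0.58 (percentile 99.0), but -0.52 with cells thinned to equal depth. Socs3 was 1081 against 792 CPM, a ratio of 1.36 (0.969 to 1.98). Stat3 had 71 counts against 1, a ratio of 3.62 (0.630 to 145), and Ascl1 had 24 against 2, 1.63-fold lower (0.187 to 6.58), so neither had a direction beyond counting error. Notch targets had a median of -1.78 (percentile 0), and Hes5, a gene of glia, stood at 9.52 against 186 CPM beside 632 against 1749 in Müller glia-like cells. Id1 was 124 against 326 CPM (104 against 14 counts), a ratio of 0.379 (0.216 to 0.718), beside 2716 against 4661 CPM in Müller glia-like cells, so for both genes RNA of glia in these droplets is not excluded as the source. JAK-STAT genes had a median of -0.39 (percentile 52.9). In this class, 1 count in early ANT stood at 23.3 CPM and so passed the bound of 10 CPM. A gene with 0 counts there had no ratio unless early ANTSi passed the floor of 69.9 CPM. Numbers of lower genes here therefore lean upward. Medians of matched random lists were themselves -0.18 for interferon-stimulated, -0.03 for MHC class I and -0.39 for Notch and JAK-STAT genes.

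The sorted ANTSi library addresses what the GFP-positive fraction held and how its neuron-like cells differed from its glia. Of 2507 cells, 44.5% were Müller glia-like (42.5 to 46.4%; 1115 cells) and 27.6% bipolar-like (25.8 to 29.4%; 691 cells), with Pcp2, Gng13, Cabp5, Grm6 and Trpm1 leading their clusters. A cluster of 111 cells, 4.43% (3.66 to 5.31%), carried markers of immature neurons and, past the same fold, 7 amacrine markers. Neuron-like cells in all were 32.0% (30.2 to 33.9%; 802 cells). A Neurog2-led cluster with Nppc and Btbd17 was 11.7% (10.5 to 13.1%; 294 cells). Microglia or macrophage-like cells were 6.34% (5.42 to 7.37%; 159 cells), rod-like cells 2.99% and cone-like cells 0.718%, although the cells were sorted for GFP. Neuron-like cells that passed the sort without arising from glia are therefore not excluded. The Müller glia-like share was 56.6% with only cells of at least 500 genes and 31.3% at a Leiden resolution of 2.

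Neuron-like cells of the sorted library differed from its Müller glia-like cells in most JAK-STAT genes and all measured Id, gliosis, immediate early and heat shock genes, which were lower, and in Neurod4 and Neurod1, which were higher, while Ascl1 was lower. This contrast is between cell types of the same library, so it cannot tell treatment from the usual difference between glia and neurons. Socs3 was 36.0 CPM in neuron-like and 2243 in Müller glia-like cells, 62.4-fold lower (50.9 to 77.4), and Id1 was 88.5 against 1683 CPM, 19.0-fold lower (16.7 to 21.8). Stat3 was 112 against 204 CPM, 1.82-fold lower (1.59 to 2.09). Ascl1 was 7.73 against 21.8 CPM, 2.81-fold lower (1.72 to 4.81). The proneural genes Neurod4, at 1414 against 8.93 CPM, and Neurod1, at 302 against 2.98 CPM, were 158-fold (116 to 223) and 101-fold higher (58.9 to 191).

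Of 16 JAK-STAT genes, 14 were lower in neuron-like cells (median -1.95, percentile 0.01), with the receptor gene Osmr 65.9-fold lower (25.6 to 243) and Socs2 1.60-fold higher (1.37 to 1.87). All 4 Id genes (median -4.23, percentile 0.27), all 17 interferon-stimulated genes (-3.87, 0), all 10 MHC class I genes (-2.34, 0.01), all 11 gliosis genes (-5.14, 0), all 16 immediate early and heat shock genes (-3.73, 0) and all 7 inflammatory cytokine genes (-4.20, 0) were lower. Id3 was 142-fold lower (110 to 186), the ceruloplasmin gene Cp 83.7-fold lower (62.7 to 114) and Zfp36 67.4-fold lower (53.4 to 86.4), while Stat1 was 1.20-fold lower (0.992 to 1.47). Of 12 Notch targets and glial regulators, 8 were lower (-2.96, 0), with Hes1 104-fold lower (40.4 to 382) and Nfia 2.08-fold higher (1.93 to 2.24). Disease-associated microglial genes (-2.21, 0), the unfolded protein response (-0.72, 1.58) and lysosomal genes (-0.43, 1.21) were also below most random lists. Neurogenic Ascl1 targets had a median of 1.04 (percentile 99.2; 9 of 16 higher), with Gadd45g 12.2-fold lower (10.9 to 13.8), and this median was -0.13 with doublets kept and stayed outside the random range in only 2 of 7 alternatives. Homeostatic microglial genes (-0.96, 6.56), S phase genes (-0.36, 6.42), cholesterol synthesis (-0.08, 7.09) and glycolysis and hypoxia (0.79, 95) lay within the range of random lists.

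Outside the lists, Edil3 was 316-fold higher in neuron-like cells (145 to 864), and Rasgrf2, Adgrb3, the dopamine receptor gene Drd1, Otx2os1, Nyap2, the potassium channel gene Kcnk3, Plch2 and the sialyltransferase genes St8sia3 and St6galnac5 were also among the 10 highest. Each of the latter had 1 to 3 counts in Müller glia-like cells, as with Drd1 at 548 against 2 counts, a ratio of 462 (127 to 3828). Cyr61 was 167-fold lower (136 to 207), Mlc1 162-fold lower (69.3 to 500.4) and Zfp36l1 155-fold lower (98.9 to 257). Ctgf had 1 count in neuron-like and 1363 in Müller glia-like cells, 808-fold lower (145 to 31919), and S1pr3, Tst, Cyp2d22, Mgst1, Runx1 and Chil1 had 1 or 2 counts in neuron-like cells. The median gene had a log2 ratio of 0.25 in this comparison and of -0.14 in the microglia-like comparison, so list medians there shift by as much under scaling by the median of ratios.

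**Figure D4:**
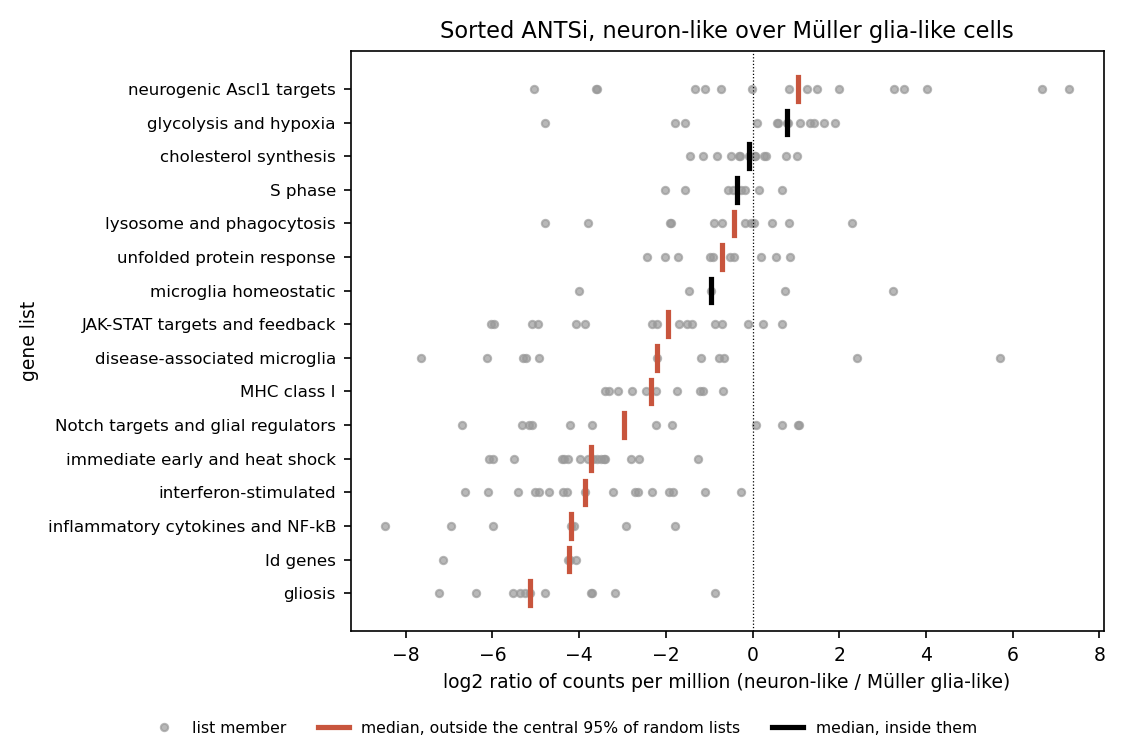
Log2 ratio of CPM, neuron-like over Müller glia-like cells of the sorted ANTSi library (horizontal axis), for each gene list (vertical axis), with points for list members and bars for medians, 1 library. Medians outside the central 95% of random lists are coloured, from -5.14 for gliosis to 1.04 for neurogenic Ascl1 targets.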

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

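The tests of matched depth, of the sexes, of clusters weighted alike and of thinned cells were chosen only after the result was seen, and the test of bipolar markers over whole libraries was not.

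More Neurog2-led and bipolar-like cells were found in early ANTSi than in early ANT, 29.5% against 10.0%, and early ANTSi also held 1106 counts of Y-linked genes, where early ANT held 0. The test of depth written beforehand, the level of 14 bipolar markers over whole libraries, gave a ratio of 1.15 (1.09 to 1.22), between the bounds set for it, and decided nothing, as 10 of the 14 were lower in early ANTSi and Otx2 (214 against 59.9 CPM) carried the ratio. Against depth as the whole cause stands the difference of 17.3 points (15.7 to 19.0) for both classes together with the depth of every cell matched before clustering, all of it named bipolar-like as no Neurog2-led cluster was found there, and against the male mice in early ANTSi stands the difference of 28.0 points (25.9 to 30.1) between its female cells and early ANT. Differences between animals that got the same treatment may be a candidate explanation, since female and male cells of early ANTSi differed by 27.1 points, more than the libraries did (19.5). That gap lies between the sexes, so it cannot tell sex, or a response that depends on sex, from other differences between animals. The STAT inhibitor stays open too, untested, because it cannot be told apart from the library and the animals with 1 library per group.

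Interferon-stimulated genes of Müller glia-like cells, set against early ANT, had medians of 0.48 with female and -2.54 with male cells of early ANTSi, on opposite sides of the random lists. Against unequal shares of glial clusters in male and female cells as the whole cause stands the male over female median of -2.20 with clusters weighted alike (-2.83 to -1.09 over resampled genes, percentile 0), although the Ifit3-led cluster held only 9 male cells. Sex itself, and differences between the mice that happened to be of each sex, stay open, untested.

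Id and MHC class I genes were lower in Müller glia-like cells of early ANTSi than of early ANT. With cells thinned to equal depth, the medians were -0.96 for Id and -0.91 for MHC class I genes. Random thinning keeps the expected share of each gene within a cell, so these values cannot decide on depth as the cause. It also left out 267 cells of early ANT and 0 of early ANTSi. Against unequal shares of glial clusters stand medians of -0.77 for both lists with clusters weighted alike. Medians of -0.87 and -0.72 with female cells alone and of -0.91 and -1.53 with male cells alone argue against a difference in only the male or only the female mice of early ANTSi. The STAT inhibitor, and the depth, animals and preparation of each library, may each be the source, untested, and cannot be told apart with 1 library per group.

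Across cell classes of the early libraries, medians of interferon-stimulated genes lay on opposite sides of the random lists, at 0.28 in bipolar-like, 0.59 in Neurog2-led and -0.97 in microglia or macrophage-like cells, a difference that was not tested. These medians were not stable: -0.38 (percentile 23.3) in microglia-like cells without 1 cell of early ANT, -0.075 with each library clustered alone and -0.42 with cells thinned to equal depth in bipolar-like cells, and -1.86 with male cells alone in Neurog2-led cells. With the gene lists kept in the clustering, the median was -0.47 in bipolar-like and -0.43 in Neurog2-led cells. Rod-like cells, which enter no comparison of gene levels, were 0.365% of early ANTSi, 4.16% of early ANT and 2.99% of sorted ANTSi. Cone-like cells were 0.469%, 0.877% and 0.718% of the same libraries. Microglia or macrophage-like cells were 6.34% of the sorted library, and their gene levels were not compared there.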

How the results depend on the processing

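The settings of female or male cells alone, Neurog2-led cells counted as Müller glia-like, clusters weighted alike, at least 5 expected counts, depth matched cell by cell, clustering together without thinning and leaving out the cell cycle cluster or 1 cell were chosen only after seeing the data, and MHC class I was added after seeing its values to the lists described here in full. In Müller glia-like cells, the medians of Id genes (-0.96 to -0.66), MHC class I (-1.53 to -0.60), Notch targets (-0.76 to -0.33) and immediate early and heat shock genes (-0.46 to -0.21) stayed negative and outside the random range in 15 of 15 alternatives each. In the sorted library, Id, interferon, MHC class I, JAK-STAT, Notch, gliosis, immediate early and heat shock, cytokine and disease-associated microglial medians did so in 7 of 7. Shares of classes and the boundary between Neurog2-led and bipolar-like cells moved most. Depth limits the bipolar-like and microglia-like comparisons, which rest on 92322 and 42903 UMIs in early ANT. For the values that follow, all differences in share are early ANTSi minus early ANT in points, other values are log2 ratios or their medians, and the cause was not tested.

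With the depth of every cell matched before clustering, the difference in Müller glia-like share was -16.4 and in bipolar-like share 17.3, and no Neurog2-led cluster was found, with a difference of 0. With both libraries clustered together without thinning, the difference was -25.6 in Müller glia-like and 18.5 in Neurog2-led share.

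At resolution 0.5, the difference in Müller glia-like share was -7.27 and in Neurog2-led share 0.903. At resolution 2, the Neurog2-led difference was 9.34, and the sorted library held 31.3% Müller glia-like and 30.1% neuron-like cells. With doublets kept, share differences were -13.9 for Müller glia-like, 14.9 for bipolar-like and 0 for Neurog2-led cells, and 27.5% of sorted cells were neuron-like. This setting returned only 3 cells to early ANTSi, 0 to early ANT and 35 to the sorted library. The clusters thus moved with almost the same cells. In bipolar-like cells the homeostatic median was then 0.063, the neurogenic median -0.11 and Id1 -0.39, and the sorted neurogenic median was -0.13.

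With at least 500 genes, the bipolar-like difference was 5.90 points, the sorted library held 56.6% Müller glia-like and 27.9% neuron-like cells, and its neurogenic median was -0.12. In Neurog2-led cells MHC class I was -0.63, Ascl1 0.16 and Psmb8 -0.34, and the interferon median of microglia-like cells was -1.26. With each library clustered alone, where a group of early ANTSi cells with glial genes was named rod-like, the Müller glia-like difference was -35.3 and the Neurog2-led difference 0. Müller glia-like medians were 0.55 for interferon and -0.60 for MHC class I. In bipolar-like cells interferon was -0.075, homeostatic 0.064, neurogenic -0.29, Id1 -0.64 and Socs3 -0.65.

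With the gene lists kept in the clustering, share differences were -13.8 for Müller glia-like and 7.44 for Neurog2-led cells, and the sorted library held 41.2% Müller glia-like and 27.8% neuron-like cells, with a neurogenic median of -0.088. The interferon median was -0.43 in Neurog2-led cells, with Isg15 at -0.35, Ifit3 at -0.34 and Psmb8 at -0.35, and -0.47 in bipolar-like cells. With Neurog2-led cells counted as Müller glia-like, the Müller glia-like difference was -6.10, the sorted share 56.2% and Ascl1 0.19.

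With the mean over cells, interferon was 0.20 in Müller glia-like and -0.072 in microglia-like cells, and the homeostatic median 0.70 in bipolar-like cells. With clusters weighted alike, Müller glia-like cells had 0.36 for interferon, -0.59 for G2 and M phase, -0.44 for Hmgb2, -1.15 for Cenpa and -0.62 for Cks2. With cells thinned to equal depth, Neurog2-led cells had 1.07 for interferon and -0.064 for gliosis, bipolar-like cells -0.42 for interferon and 0.80 for homeostatic genes, and microglia-like cells -1.29 for MHC class I and -0.52 for G2 and M phase. The homeostatic median of bipolar-like cells was 0.66 both with members of at least 50 CPM and with at least 5 expected counts, and with the latter the JAK-STAT median of microglia-like cells was 0.23.

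With female cells of early ANTSi alone, share differences were -26.9 for Müller glia-like, 10.0 for bipolar-like and 18.0 for Neurog2-led cells, and the interferon median of Müller glia-like cells was 0.48. With male cells alone, they were 2.84 for Müller glia-like, -0.18 for bipolar-like, 1.05 for Neurog2-led and 1.32 for microglia-like cells. Müller glia-like cells then had -2.54 for interferon, -1.53 for MHC class I, -0.44 for neurogenic targets, -0.39 for Ifit2 and -2.35 for Bst2. Neurog2-led cells had 0.53 for JAK-STAT, -1.86 for interferon, -0.33 for Id, 0.039 for immediate early and heat shock genes, -1.79 for Isg15, -3.96 for Ifit3 and -0.057 for Tmsb4x. Bipolar-like cells had -0.15 for interferon, 0.76 for homeostatic, 0.73 for neurogenic genes and -0.67 for Id1, and microglia-like cells -1.58 for interferon, -3.40 for Id and -0.58 for G2 and M phase.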

Other observations

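The values of individual genes and of male and female cells given here were chosen only after the result was seen. Over whole early libraries, the 14 bipolar markers went both ways, with 4 higher and 10 lower in early ANTSi than in early ANT. The transcription factor genes Otx2 and Isl1 were 3.58-fold (3.08 to 4.17) and 2.90-fold higher (2.05 to 4.25) in early ANTSi, and Neurog2 was 106 against 21.1 CPM, 5.04-fold higher (3.93 to 6.56). Grm6, the glutamate receptor gene of ON bipolar cells, was 10.4-fold lower (6.29 to 17.3; 29 against 41 counts), Pcp2 8.06-fold lower (6.42 to 10.1; 150 against 165 counts) and the channel gene Trpm1 5.07-fold lower (3.52 to 7.27). Ascl1 was 171 against 152 CPM.

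Within early ANTSi, Müller glia-like cells of male mice had higher cell cycle and gliosis genes and lower interferon, MHC class I and neurogenic genes than those of female mice, but they also lay in other clusters. The cluster led by Clu and Dio2 held 234 of 494 male and 317 of 1488 female cells, that with cell cycle genes 44 and 32, and an Ifit3-led cluster 9 and 173. With clusters weighted alike, medians were -2.20 for interferon (percentile 0), -0.73 for MHC class I (0), -0.24 for neurogenic targets (0.06) and 0.30 for gliosis (100), but -0.33 for G2 and M phase genes (0.24). S phase genes then lay within the random range (0.07, 81.6). Outside it also lay immediate early and heat shock genes (0.23, 100), the unfolded protein response (0.23, 99.88) and Notch targets (-0.16, 0.63). Over the whole class, all 19 interferon-stimulated genes were lower, with Isg15 at 21.4 against 515 CPM, 24.1-fold lower (19.0 to 30.9). All 10 MHC class I genes (median -0.86, percentile 0) and 13 of 14 neurogenic Ascl1 targets (median -0.58, percentile 0) were lower, with the Notch ligand gene Dll3 3.12-fold lower (2.34 to 4.24), and Ascl1 was 54.7 against 105 CPM, 1.92-fold lower (1.63 to 2.27). The natriuretic peptide gene Nppc was 3.97-fold lower (3.62 to 4.36) and Btbd17 2.92-fold lower (2.75 to 3.11). All 13 measured G2 and M phase genes were higher (median 1.39, percentile 100), as were 11 of 13 gliosis genes (median 0.57, percentile 100), with cyclin D1 (Ccnd1) 2.78-fold higher (2.65 to 2.91) and Nupr1 3.92-fold higher (3.64 to 4.21). JAK-STAT genes (median -0.02, percentile 45.4) lay within the range of random lists. The sorted library held 2672 Y-linked counts and 5 Xist counts.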
